A study of Mus musculus with 8 samples.

How the data were processed

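Gene expression was measured in 8 pools of mouse metanephric kidney anlagen, the tissue from which the permanent kidney forms, dissected at embryonic day 10.25 (8 to 13 tail somites). Per the labels' protocols each sample was a pool of 16 kidneys of a single genotype, and its amplified, digoxigenin-labelled cRNA was hybridised to a one-colour Applied Biosystems Mouse Genome Survey array. There were 4 pools of Wt1 mutants and 4 control pools. The titles call the control pools wild type, while their genotype entry reads Wt1 heterozygote, so they are called controls here and their genotype is left open. No label states whether the pools came from separate litters, so p-values measure the spread between these pools, part of which may be technical.

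Per the file headers, the deposited files give 4 quantities per probe: a signal, a signal-to-noise score, a whole-number quality flag and an array-normalized signal. The deposited signal is an intensity on a linear scale. Its lowest values lay between 22.6 and 59.6 on the 8 arrays and none was negative, so it was taken as already background corrected, which no header or label states. The deposited array-normalized signal is that intensity divided by a factor whose CV within an array was 0.98% to 2.72% on 6 arrays, 8.31% in mutant pool 2 and 6.15% in control pool 2. The deposited table for the whole series held the array-normalized signal, in 264096 of 264096 cells, and not the signal used for the main comparison. The deposited signal-to-noise score and the other deposited value, the flag, were used only to filter probes. The reader software, its version and the meaning of each flag are not given in the sources used here. The choice of the signal in place of the array-normalized signal was made after the columns had been seen and before any fit.

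Log2 signals were quantile normalized over all 33012 probes in R 4.3.3 with limma 3.58.1. A probe was tested if its signal-to-noise was at least 3 and its flag under 5000 in at least 3 of the 4 pools of a genotype, which kept 17594 probes. Mutant and control pools were compared with limma's linear model and empirical Bayes step, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A difference is the log2 signal in mutants minus that in controls, and errors are SDs over 4 pools or the model's SE. Where a probe was below the detection limit in every pool of a genotype, its fold is given as a floored fold. That is the mean of the bright genotype against a floored mean of the dim genotype. Per array of the dim genotype, the floored mean took the higher of the lowest detected signal and the probe's own signal. Detection was judged per probe by signal-to-noise, so an undetected probe could lie above that lowest signal. Its floored fold is then the plain fold between means, and it is not a strict limit on the change. Between 52.6% and 59.5% of probes were detected per array. The number of arrays limits the precision.

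The files identify a probe by a gene or transcript identifier without a symbol. Symbols were taken only from the RefSeq table of assembly GRCm38.p6, by transcript accession without its version or by exact synonym. In this way 317 probes were matched to 311 genes, of which 177 probes for 173 genes were tested, 1.01% of all tested probes. None of the 27930 probes with an mCG identifier and none of the 4181 with an AK accession was matched. The files name no genome build, so no positions are given. No probe was matched to Wt1, and the targeted gene is not analysed here.

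Before the data were examined, the model, the probe filter, 28 gene lists (494 genes), the alternatives and the rule for named genes were fixed. The FGF and BMP lists were written with knowledge of the pathways that the study went on to examine. The rule names up to 12 rises and 12 falls past the threshold with a symbol and no overlap between genotypes. With fewer than 6 in a direction it also names up to 8 genes of smallest p, as not having passed, and up to 4 measured members of each list. Where a gene had several probes the brightest was named. A set test needed 5 tested members, which 0 of the 28 lists had, so none was run. In their place 7 groups were formed from the matched symbols after the data had been seen, and up to 2 genes of smallest p were named from each. For unmatched identifiers the largest 2 falls and 2 rises are given, also chosen after the data had been seen.

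The array names carry 2 dates. One date holds 3 mutant and 3 control pools, and the other holds mutant pool 1 and control pool 2. The date was tried as a block and the larger date by itself. Other alternatives changed the scaling, the values, the background correction, the filter, the variance model, the array weights and the replicate number, averaged the 2 mutant pools whose array names share a number, or left out single pools. The replicate numbers are those of the titles, which differ from those in the array names. Mutant pools 1 and 4 are the 2 whose array names share a number, and whether they are repeat arrays of 1 pool is not settled by the labels. They are counted as separate pools, as their titles number them, and n = 4 rests on this. Leaving out control pools 1 and 2, or 3 and 4, and adjusting over the matched probes alone were added after the data had been seen. The model was tested on simulated data with the pools' own spread over 17594 probes. It recovered 8.96% of changes of 0.5 on the log2 scale, 58.2% of changes of 1 and 86.4% of changes of 2. Of the 115 simulated probes it called, 13 carried no change, more than the nominal share of 5%. The simulated spread was drawn independently for each probe and array. It therefore lacks any deviation that control pools 1 and 2 share across probes, and the error rate in the real data may differ.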

Results

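The data set asks which transcripts differ in the kidney-forming region when Wt1, a zinc finger transcription factor required for kidney formation, is disrupted, at a stage that the submitters place ahead of the cell death seen in mutants. It holds 8 arrays, with 4 pools of mutant and 4 pools of control anlagen. The median signal per array ran from 681.6 in control pool 2 to 2118.2 in control pool 1. Between 17349 and 19633 probes were detected per array. Wt1 itself was not matched to a probe and is not analysed here, so the genotype labels were not checked by the targeted gene.

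The control pools differed among themselves more than the mutant pools did. The median SD of a tested probe was 0.287 on the log2 scale among controls and 0.136 among mutants. Mutant pools correlated with one another at r = 0.986 to 0.988 across probes, which are not independent replicates. Control pool 1 correlated with the mutants at 0.974 to 0.975 and control pool 2 at 0.963 to 0.967, while the correlation between these 2 controls was 0.986. Control pools 3 and 4 correlated with each other at 0.988, and with the mutants at 0.981 to 0.985. Control pool 2 correlated with control pools 3 and 4 at 0.962 and 0.961, below its values with the mutants. Control pool 1 correlated with control pools 3 and 4 slightly above its values with the mutants. Control pools 3 and 4 thus correlated higher with every mutant pool than with control pools 1 and 2, which limits any reading by genotype. The first principal component held 42.4% of the variance and separated control pools 1 and 2, at 42.16 and 67.46, from the other arrays, which lay between -21.5 and -13.08.

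**Figure D1:**
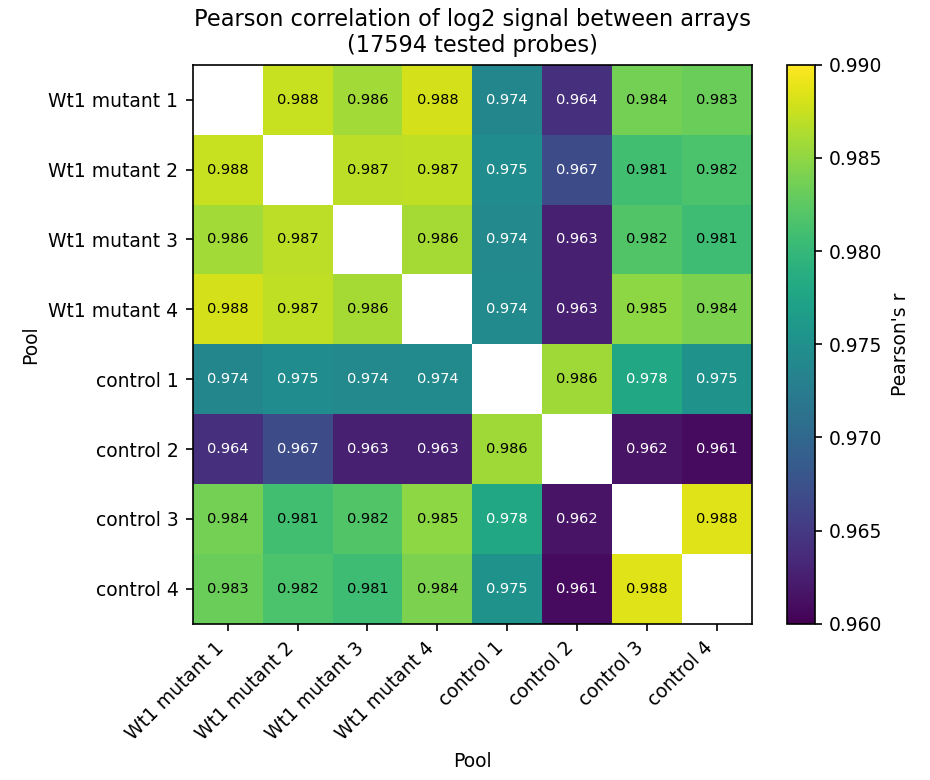
Pearson correlation of log2 signal between each pair of the 8 pools over the tested probes, with pools on both axes and r as colour and number. Control pools 1 and 2 correlate with each other at 0.986, and control pool 2 with the mutant pools at 0.963 to 0.967.

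Of 17594 probes tested, 81 differed between mutant and control pools in limma's test, 12 higher and 69 lower in mutants. The largest fall was at mCG5838.1, from 13.66 ± 0.43 in controls to 9.49 ± 0.41 in mutants (log2 signal, SD, n = 4). This was a difference of -4.17 (SE 0.26), an 18.0-fold lower signal, with limma's adjusted p = 0.000582. The probe for mCG145587 was detected in all 4 control pools and in 0 of 4 mutant pools. Its floored fold was 11.9, lower in mutants (limma's adjusted p = 0.00491 for the plain difference). The largest rise in mean signal was at mCG127999.1, with a difference of 2.03 (SE 0.33, limma's adjusted p = 0.0469). It was detected in 1 of 4 control pools. The call was lost under 16 alternatives, among them leaving out any 1 of the 8 pools (limma's adjusted p from 0.0583 without control pool 3 to 0.143 without mutant pool 2). With 1 pool left out the difference ran from 1.83 to 2.22, and within the larger date it was 2.30. The signal for mCG13730.1, detected in 0 of 4 control pools, was 3.59-fold higher in mutants (limma's adjusted p = 0.00463). This floored fold equals the plain fold between means. With control signals mostly below detection, which of these 2 rises is larger is not settled. The files do not pair these identifiers with gene symbols.

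Among the 69 falls, 51 were at least 2-fold and 10 at least 4-fold, and 9 of the 12 rises were at least 2-fold. The median called fall was -1.30 and the median called rise 1.11 on the log2 scale. In 11 falls the probe was below detection in all 4 mutant pools, with floored folds from 2.02 to 11.9, which are not strict limits. All 81 called probes were without overlap between genotypes, as were 10.6% of all tested probes, against 2.9% by chance. Of the 81, 71 carried an mCG identifier and 10 a cDNA accession, and 0 were matched to a symbol. The count was 63 with the array date as a block and 30 within the larger date (3 pools of each genotype). The smaller date, with mutant pool 1 and control pool 2, allows no test. The fit within the larger date is therefore also a fit without these 2 pools. With mutant pools 1 and 4, whose array names share a number, averaged as 1 sample, the count was 36. The count depended on which control pools entered: without control pools 1 and 2 it was 89, of which 36 were higher and 53 lower and 42 were shared with the 81, and without control pools 3 and 4 it was 4566, of which 2115 were higher and 2451 lower, both chosen after the data had been seen. Leaving out 1 pool gave 38 without mutant pool 1, 48 without mutant pool 2, 47 without mutant pool 3, 38 without mutant pool 4, 44 without control pool 1, 65 without control pool 2, 49 without control pool 3 and 64 without control pool 4. Without control pools 1 and 2 the difference was -3.87 for mCG5838.1, -3.45 for mCG145587 (-3.62 with all pools), 1.73 for mCG13730.1 (1.84 with all pools) and 1.96 for mCG127999.1. For mCG145587 and mCG13730.1 these are plain differences of means, without the floor, that include signals below detection. The adjusted p in limma's test, with fewer pools, was then 0.019, 0.0633, 0.0542 and 0.0999, and within the larger date it was 0.0797 for mCG145587 and 0.0682 for mCG13730.1.

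**Figure D2:**
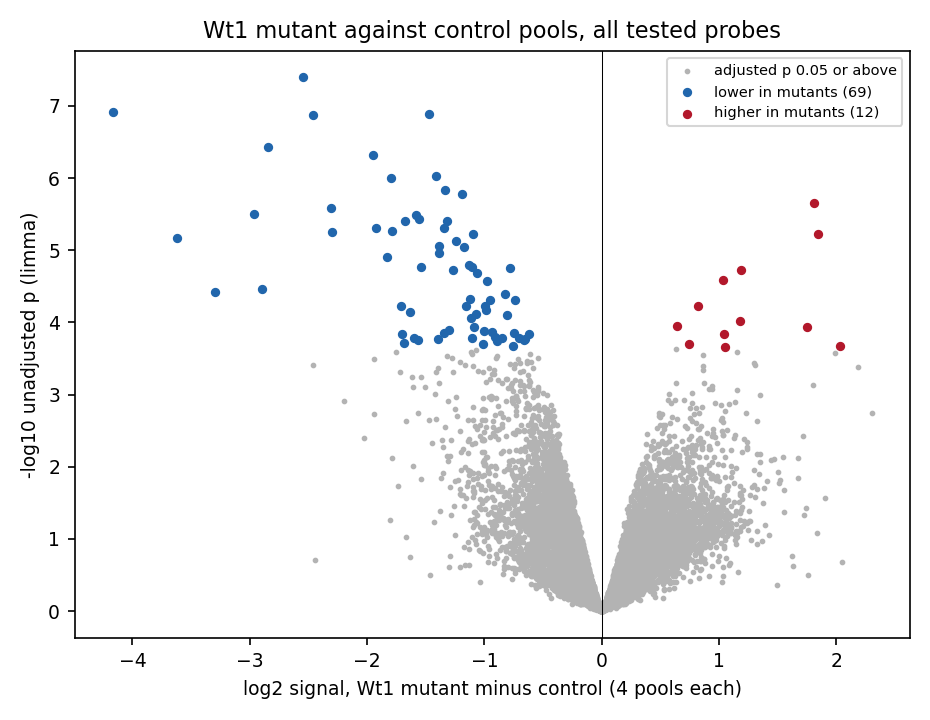
Each point is a tested probe, with the log2 difference between mutant and control pools on the x axis and the -log10 of limma's unadjusted p on the y axis. The 69 probes lower in mutants are blue, the 12 higher ones red, and the rest grey.

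None of the 177 tested probes with a matched symbol passed the threshold in limma's test over all probes, against 81 of 17594 tested probes. At that share 0 of 177 is not unusual, so it does not show that the matched genes are unaffected. Of the 177, 28 had an unadjusted p under 0.05, 11 higher and 17 lower, against 2383 of all 17594 tested probes. The smallest adjusted p in limma's test was 0.0701, for Krt23, a type I keratin. Its signal was 11.50 ± 0.40 in controls and 9.77 ± 0.61 in mutants (log2, SD, n = 4), a difference of -1.72 (SE 0.32). It was detected in all 4 control and 0 of 4 mutant pools, with a floored fold of 3.3 that equals the plain fold. Ntn1, which encodes the secreted guidance cue netrin-1, measured 13.58 ± 0.33 in controls and 12.62 ± 0.19 in mutants, a difference of -0.95 (SE 0.18, limma's adjusted p = 0.0822). Rasd1, a Ras-related GTPase induced by glucocorticoids, measured 12.61 ± 0.17 and 11.99 ± 0.12, a difference of -0.62 (SE 0.12, limma's adjusted p = 0.0899). Over all probes, Krt23 passed the threshold within the larger date, with the replicate block and without mutant pool 1 (-2.02, limma's adjusted p = 0.0254), Ntn1 with a trended, robust variance and without control pool 4 (-1.09, limma's adjusted p = 0.0452), and Rasd1 with array weights, and all 3 passed without control pools 3 and 4. When the adjustment ran over the matched probes alone, a choice made after the data had been seen, these 3 had an adjusted p of 0.0455 in limma's test. With control pools 1 and 2 left out the same adjustment called 0 matched probes, and over all alternatives its count ran from 0 to 65. The difference without control pools 1 and 2 was -1.775 for Krt23, -0.709 for Ntn1 and -0.698 for Rasd1. The differences of Krt23 and Rasd1 were thus no smaller there, while the fit had fewer pools.

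The other genes of smallest p with a lower mean signal in mutants were Psme3, a proteasome activator subunit (-0.51), Ldhal6b (-0.39), the orphan receptor Gpr173 (-1.32, detected in 1 mutant and 3 control pools), Nat8f2 (-0.60) and the pyridoxal phosphatase Pdxp (-0.38). Those with a higher mean were the clustered protocadherin Pcdha3 (0.86), the chemokine Ccl21a (0.77), Mab21l1 (0.84), the alpha globin Hba-a1 (0.98), Ramp3 (0.54), the mitochondrial dehydrogenase Hsd17b10 (0.43), the galectin Lgals1 (1.07) and the prefoldin subunit Pfdn5 (0.86). Their adjusted p in limma's test ran from 0.123 for Pcdha3 to 0.347 for Pfdn5. Without control pools 1 and 2 the difference was 0.41 for Hba-a1, 0.32 for Lgals1, 0.16 for Pfdn5, 0.19 for Hsd17b10 and 0.24 for Ramp3. It was 0.48 for Ccl21a, -0.31 for Psme3, -0.22 for Pdxp, 1.10 for Mab21l1 and 0.60 for Pcdha3. It was -0.45 for Ldhal6b, -0.93 for Gpr173 and -0.41 for Nat8f2. Without control pools 3 and 4 it was 1.56 for Hba-a1, 1.82 for Lgals1 and 1.55 for Pfdn5, which passed the threshold there. Psme3, Gpr173, Nat8f2, Pdxp, Pcdha3, Ccl21a, Ramp3 and Hsd17b10 also passed there, while Ldhal6b and Mab21l1 did not. That comparison has control pools 1 and 2 as its only controls, so it also carries the deviation these pools share. Ccl21a has a near-identical copy, Ccl21b, whose 2 probes differed by 0.67 (0.30 without control pools 1 and 2, 1.05 without control pools 3 and 4, 0.45 without control pool 2) and -0.09, so its value is uncertain.

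**Figure D3:**
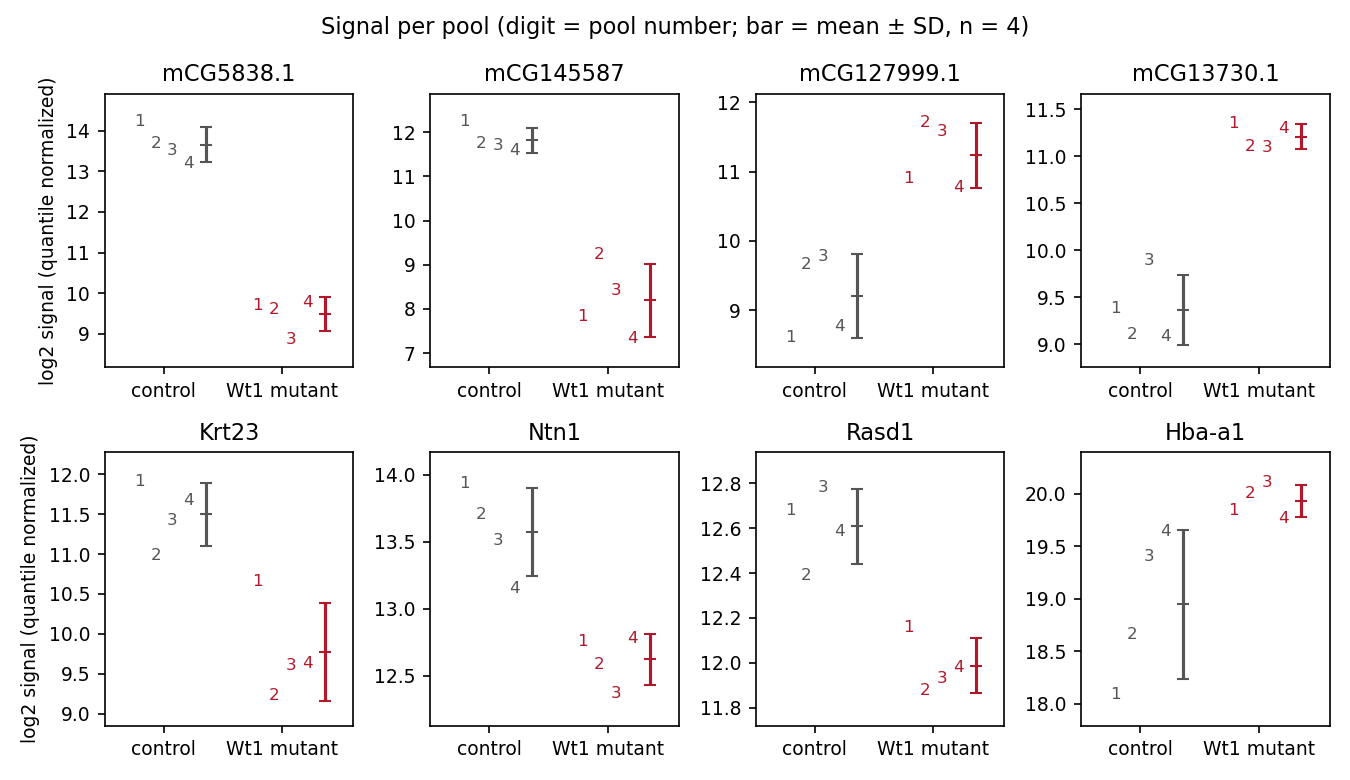
Log2 signal per pool for 4 identifiers and 4 named genes, with each pool drawn as its number and the bar giving mean ± SD (n = 4); the y axes differ between panels and do not start at 0. For Hba-a1 the control pools spread with an SD of 0.71, against 0.15 in the mutant pools.

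Of the 28 gene lists, 6 had a member that was matched to a probe, 1 gene each, and 0 had enough members for a test. The FGF, BMP, nephron progenitor, ureteric bud, apoptosis, cell cycle, ribosomal protein, endothelial, leukocyte and germ cell lists had 0 matched members, as did the other lists without a located gene, so these programmes are not analysed here. Among the 6 located genes, Hba-a1 from the red cell list is given above. Mapk7, a MAP kinase also called ERK5, differed by -0.34 (SE 0.13, limma's adjusted p = 0.325). It was the only tested member of the list of epicardial and podocyte genes reported under WT1 control. Notum, a secreted Wnt inhibitor, differed by 0.34 (SE 0.16, limma's adjusted p = 0.379), and Jun, an immediate early gene, by 0.09 (SE 0.11, limma's adjusted p = 0.677). The value for Jun was 0.04 without control pool 1, 0.05 without mutant pool 4 and 0.14 without control pool 3. Lhx2 and Sox3, developmental transcription factors, were each detected on 1 array, a control, and were not tested. Mapk7 and Notum passed the threshold without control pools 3 and 4, at -0.51 and 0.58, and lay at -0.17 and 0.11 without control pools 1 and 2.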

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

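The first fits had been run, and control pools 1 and 2 seen to stand apart, before any of these tests was written down. The tests of the array date, of gene length and of the spread added by control pools 1 and 2 were chosen only after the results they bear on had been seen. The test of mislabelled mutant tissue was written before its own value was known, but for a pattern already seen and on probes called in an alternative that was not planned. The interval around the position of each control pool was also added after its first value had been seen, and made that test stricter.

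Ramp3 in mutant pool 4 had a log2 signal of 12.07, below the other mutant pools, which lay between 12.24 and 12.27. Magel2 in mutant pool 4 had a log2 signal of 12.37, above the other mutant pools, which lay between 11.94 and 11.96. These were the 2 values that stood far from the rest of their group in 70 groups of 4 that were checked, and chance gives about 1 in 20 groups, or 5%.

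The 81 probes that differed between genotypes exceeded what other groupings of the arrays gave. In 1 of the 35 splits of the 8 pools into 4 and 4, the real one, as many probes passed, and the highest count in any other split was 1. A share of 1 in 35 is the smallest these splits can give, so they do not exclude chance in how the pools fell into groups. They treat the pools as exchangeable, and ignore the array date and the possible repeat of mutant pools 1 and 4. Keeping the dates balanced would leave fewer splits. The splits do not show which transcripts depend on genotype, since the controls are themselves uneven.

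Control pools 1 and 2 stood apart from the other 6 arrays. The array date argues poorly for this, since control pool 2 correlated at 0.964 with the mutant pool of its own date and at 0.986 with control pool 1 of the other date. That control pools 1 and 2 were whole mutant pools labelled as control is also argued against. The scale put mutants at 0 and control pools 3 and 4 at 1, over the 89 probes called without pools 1 and 2. Control pool 2 had a median position of 0.787 (bootstrap interval 0.584 to 0.912) and control pool 1 of 0.881 (0.675 to 1.03). Of the 89 probes, 56 put control pool 2 and 66 put control pool 1 nearer the other controls. The interval resamples probes, which are not independent. Control pools 3 and 4, which set the scale, were not tested for this. The quartiles of the position were 0.171 and 1.054 for control pool 2, and 0.479 and 1.223 for control pool 1. A pool that held some mutant tissue could lie between 0 and 1, so a mixed pool is not addressed by this test. A length bias of amplification or labelling stays open: across 173 matched genes, the deviation of control pool 2 followed genomic gene length with a Spearman rho of 0.257 (permutation p = 0.00062, adjusted 0.005 over 8 arrays) and that of control pool 1 with 0.187 (permutation p = 0.014, adjusted 0.028), which is short of the size set for the test. The other 6 arrays had negative values. These were -0.215 for control pool 3 (permutation p = 0.0043, adjusted 0.017) and -0.189 for control pool 4 (permutation p = 0.013, adjusted 0.028). In the mutant pools they ran from -0.171 to -0.076. Deviations from a common mean sum to 0, so part of this opposite sign is built in. These values therefore cannot show whether a relation to length is particular to control pools 1 and 2. Genomic length is also a rough stand-in for transcript length. No biological explanation was tested, and a difference in the embryos or dissections behind control pools 1 and 2 stays possible.

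Most called probes were lower in mutants, 85.2% of 81. Scaling between arrays is argued against, as the share under the 3 other scalings ran from 79.3% to 87.7%. Without control pools 1 and 2 the share was 59.6% and 36 probes were called higher, so a candidate explanation is that the spread these pools add hides rises more than falls. Without control pools 3 and 4 the share was 53.7%, of 4566 called probes, so these values do not single out control pools 1 and 2, and the other pairs of controls were not left out. With array weights, which weighted control pools 1 and 2 at 0.305 and 0.161, the share was 63.9% (103 higher and 182 lower). With 1 control left out the share was 86.4%, 75.4%, 87.8% and 85.9% for control pools 1 to 4, and a true excess of falls in mutants stays open.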

How the results depend on the processing

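Leaving out control pools 1 and 2, or 3 and 4, and adjusting over the matched probes alone were chosen after the data had been seen; the other alternatives were planned. The count of 81 moved by over 1.5 times under these: 4566 without control pools 3 and 4, 285 with array weights (103 higher, 182 lower), 36 with mutant pools 1 and 4 averaged, 30 without a filter on dim probes, 30 within the larger date and 30 with the replicate block. Leaving out 1 pool gave 38 to 65, and 32 of the 81 were called in each of these. By construction the counts of 30, 36 and those with 1 pool left out rest on fewer pools, fewer residual degrees of freedom or more tested probes, and the array weights of control pools 1 and 2 were 0.305 and 0.161. For the count of 4566 the only controls were pools 1 and 2, which stood apart from the other arrays on the first principal component. Their shared deviation therefore enters that comparison, and probes that passed there cannot be read as differences between genotypes alone. What lies behind the deviation was not settled by the tests of array date, mislabelled pools and gene length given above. No biological explanation of it was tested. Under the remaining alternatives the count ran from 63 (date block) to 99 (trend and robust variance). The filter without the flag removed no further probe and says nothing about stability.

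The replicate numbers of the titles, which differ from those in the array names, did not pair the pools, and pairing by the array names was not examined: same-numbered pools deviated together with r = -0.087, 0.178, 0.004 and 0.078, and only number 2 correlated best with its own number. Mutant pools 1 and 4 correlated at 0.988, against 0.9858 to 0.9875 for other mutant pairs.

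Frat2, at -0.12, reversed to 0.14 with array weights and to 0.211 without control pools 1 and 2, and ran from -0.315 to 0.036 with 1 pool left out, above 0 without control pool 1. Krtap4-2, at 0.05, reversed to -0.032 without control pools 3 and 4 and ran from -0.23 to 0.239 with 1 pool left out, below 0 without mutant pool 3 and without control pool 1. The Ccl21b probe at -0.09 reversed to 0.078 without control pools 3 and 4, was -0.262 without control pools 1 and 2, and ran from -0.195 (without control pool 2) to -0.024 (without control pool 3) with 1 pool left out, so its size depends on single pools. The cause was not tested. Across named genes 765 values kept direction and side of the threshold, 25 passed it newly, mostly without control pools 3 and 4, where the median of all probes lay at -0.137 in place of -0.0583, and 20 lost it, 16 of these for mCG127999.1. Over the matched probes alone, 15 of 25 alternatives called at least 1 probe (Krt23 in 11, Ntn1 in 8, Rasd1 in 9). Not run for lack of matched genes: the Wt1 and gene list alternatives and the set tests. The alternative rule for genes with several probes was also not run. For the 11 falls below detection in all mutant pools the size is uncertain, since a floored fold is not a strict limit.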

Other observations

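The 7 groups below were formed from matched symbols after the data had been seen, and 0 of their tested probes passed the threshold in limma's test over all probes, so their values are descriptive.

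All 6 imprinted genes with a matched probe were detected on all 8 arrays. Their differences ran from -0.44 for Ube3a to 0.52 for Magel2, with a median of -0.05, and 0 had an unadjusted p under 0.05. Without control pools 1 and 2 the value was -0.06 for Ube3a and 0.76 for Magel2, and Ube3a was at -0.23 without control pool 2. Without control pools 3 and 4 it was -0.83 for Ube3a (limma's adjusted p = 0.0126), 0.29 for Magel2 and -0.42 for Gnas (limma's adjusted p = 0.0309, against -0.10 with all pools), so Ube3a and Gnas passed the threshold there. In the FGF and MAP kinase group, 4 of 7 genes were tested, with a median difference of -0.30. In limma's test 2 had an unadjusted p under 0.05, Mapk7 and Rasd1, which is a Ras-related GTPase and not an FGF or MAP kinase. The other tested genes were Mapk1ip1, at 8e-04, and Fgf11, at -0.26. The Fgf11 difference rests on control pool 4, at 12.57, with the other controls at 11.59 to 11.65 and the mutants at 11.42 to 11.84. Mapk7 was -0.17 without control pools 1 and 2, and -0.51 without control pools 3 and 4, where it passed. In the Wnt group 2 of 3 genes were tested, Notum at 0.34 and Frat2 at -0.12. Frat2 was at 0.21 without control pools 1 and 2 and at -0.46 without control pools 3 and 4. Of 15 developmental and signal-dependent transcription factor genes, 9 were tested with 10 probes, with a median of -0.11, and 1 had an unadjusted p under 0.05, Elf4 at -0.61 (limma's adjusted p = 0.305), or -0.38 without control pools 1 and 2 and -0.83 without control pools 3 and 4, where it passed (limma's adjusted p = 0.0442). Pou3f3, a POU-domain factor expressed in the developing kidney, was at -0.43, at -0.01 without control pools 1 and 2, at -0.86 without control pools 3 and 4, at -0.26 without control pool 1 and at -0.23 without mutant pool 2. Of 10 immune genes 4 were tested with 5 probes, and 2 probes had an unadjusted p under 0.05, 1 for Ccl21a and 1 for Ccl21b. Bcl2a1b was at 0.34, at 0.06 without mutant pool 1 and at 0.51 without mutant pool 3.

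Some matched genes are known mainly from other organs. Of 52 probes for 51 chemosensory receptor genes, 35 were detected on no array, and 4 were detected on all 8 arrays and tested. Of 13 milk protein, hair keratin and keratin-associated protein genes, 9 were detected on no array, and 2 were detected on all 8 arrays and tested. Krtap3-3 differed by -0.10 (-0.07 without mutant pool 3, -0.06 without control pool 4). Krtap4-2 differed by 0.05, and ran from -0.23 without mutant pool 3 to 0.239 without mutant pool 4, so its direction is not settled.

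Of the tested probes, 2187 share an identifier with another. Among them 5 were called, from 4 identifiers, 1 of which had 2 called probes. The 4 other probes of these identifiers were not called, had the same sign in 4 of 4 cases, and 2 had an unadjusted p under 0.05.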
